A study of Sus scrofa with 6 samples.

How the data were processed

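Total RNA of 6 pig cell samples was labelled with biotin and hybridised to the Affymetrix Pig Genome Array, per the labels' protocols. Cells were grown in DMEM with 15% FBS, and the iPS lines on mouse feeder cells. The deposited value table holds log2 values for 24123 probe sets on 6 arrays with 0 missing values. The software, background correction, summarization, normalization and baseline the authors used are not given in the sources used here.

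The values are positive and negative and centred near 0, so every probe set has its own zero. Array medians were -0.06 in PEF, 0.70 in PAFSC, 0.05 in PS24, 0.00 in 30AC5, 0.02 in iPF4-2 and 0.01 in iPSCs-w. The baseline stays unknown, and so does any scaling between arrays. Differences between arrays of one probe set are readable, and levels of different probe sets are not. The rules below that use a mean over the arrays (the choice of 1 probe set per gene, the filter on low means and the matching of random lists) were written for expression levels and here act on relative values.

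The 124 array control probe sets were left out, which left 23999; 64 reporter probe sets stayed in the tests. The platform annotation gave 1 gene symbol to 10069 of these, several to 198 and none to 13732, for 6765 different symbols. Through gene IDs, 9961 probe sets were found in the RefSeq gene table, and 0 had another symbol there. A probe set with several symbols was not named.

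Samples were grouped by the labels into somatic cells and 3 iPS marker classes. The tests used R 4.3.3 and limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all probe sets, threshold 0.05). The iPS against somatic comparison set 4 lines against 2 samples with 4 residual degrees of freedom. The comparison of SSEA1-labelled lines with SSEA3/SSEA4-only lines, and of each line with the other 3, used 3 classes and 3 residual degrees of freedom. PEF and PAFSC were compared without a test, and planned percentiles of list medians among random lists are not given, since the mean used for matching holds the compared values. Gene lists were tested with camera at a preset correlation of 0.01 over the 25 of 30 lists that had 5 or more measured genes, with 1 probe set per gene (highest mean). Of 480 genes in the lists 272 were measured. With a correlation estimated per list, camera also uses the residual degrees of freedom of the arrays. A call lost there can come from the few arrays as well as from correlated genes.

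Before the data were examined, the comparisons, the lists and the rule for named genes were fixed. For iPS against somatic, up to 12 genes per direction past the threshold and without overlap were named, filled by the smallest p among genes without overlap. For the other contrasts it was up to 6 per direction, or, where none passed, the 4 largest differences without overlap among genes in the upper 50% by mean. For PEF against PAFSC it was the 6 largest per direction, and for each list the 4 members with the largest change against somatic. A part of these is printed. The genes of the comparison with PEF alone were added later.

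Alternatives were quantile normalization, median centring, a filter on the lowest 40% by mean, a floor at the 25th percentile, eBayes with a trend or robust (statmod 1.5.0), treat against a log2 change of 1, 1 probe set per gene, 4 classes, only the 4 iPS lines, fry, an estimated correlation, the mean of a gene's probe sets, Spearman correlation and leaving out each sample. Leaving out PAFSC and PS24 together was added after seeing the data.

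The tests were checked on simulated data, with 50 of 23999 probe sets changed at each size. Values were drawn independently, with the residual SD of each probe set taken as equal on all arrays. The wider spread of the PAFSC array was therefore not simulated. For iPS against somatic, limma called 0% of those changed by 1 log2 unit, 2% at 2, 32% at 4 and 70% at 6. Without PAFSC it called 2%, 20%, 50% and 78%. For the SSEA1 comparison it called 0% at each size, and without PAFSC 0%, 0%, 52% and 56%. In the list test, camera called the 1 shifted list and 0 of 24 others. The simulated genes were independent, so this says nothing about false calls in lists of correlated genes.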

Results

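Gene expression was measured in 6 pig cell samples on the Affymetrix Pig Genome Array, with 1 array per sample. There were 2 somatic samples: PEF, an embryo fibroblast culture, and PAFSC, a culture of amniotic fluid stem cells. The other 4 were induced pluripotent stem (iPS) cell lines, which the labels separate by the stage-specific embryonic antigens on their surface. These antigens (SSEA) are glycan epitopes used as markers of pluripotent cells. PS24 was positive for SSEA1, SSEA3 and SSEA4, 30AC5 for SSEA1, and iPF4-2 and iPSCs-w for SSEA3 and SSEA4. The iPS lines were grown on mouse embryo fibroblast feeders. The series set iPS lines of one laboratory beside lines from others, which differed in marker expression and plasticity, but the labels do not say which line came from where.

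The values are log2 values relative to a baseline of each probe set, so a value can be set against the same probe set on another array but not against another gene. Each line is 1 sample, and limma p-values measure the spread between these samples, which were not stated to be repeated cultures. Camera p-values set the genes of a list against all other genes. At the preset correlation they count genes rather than arrays, so a small value does not measure the spread between samples. The number of arrays limits the precision. The PAFSC array stood apart: the SD over its 23999 probe sets was 2.01, against 0.808 for PEF and 0.610 to 0.729 for the iPS lines. Its median was 0.70, and 2064 of its values lay below -3.

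The first question was how the iPS lines differed from the somatic cells. The mean over the 4 iPS lines was lower for 23 of 23 fibroblast genes and 9 of 9 contractile genes, and against PEF alone for 19 of 23 and 9 of 9. S100A4, a calcium-binding protein common in fibroblasts, was 5.23 in PEF and 5.19 in PAFSC, and -0.20 ± 0.62 (SD, n = 4) in the iPS lines. It fell by 5.41 on the log2 scale (SE 0.54, limma adjusted p = 0.0300) and was the 1 named gene past the threshold. Below both somatic samples in every line lay 14 of the 23 and 6 of the 9; LUM, a matrix proteoglycan, was 3.77 in iPF4-2 against 1.59 in PAFSC. DCN, the matrix proteoglycan decorin, differed by -5.39 (SE 1.02, limma adjusted p = 0.151). PRRX1, a mesenchymal transcription factor, differed by -5.53 (SE 1.20, limma adjusted p = 0.184), and FBN1, the microfibril protein fibrillin, by -4.40 (SE 1.00, limma adjusted p = 0.193).

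**Figure D1:**
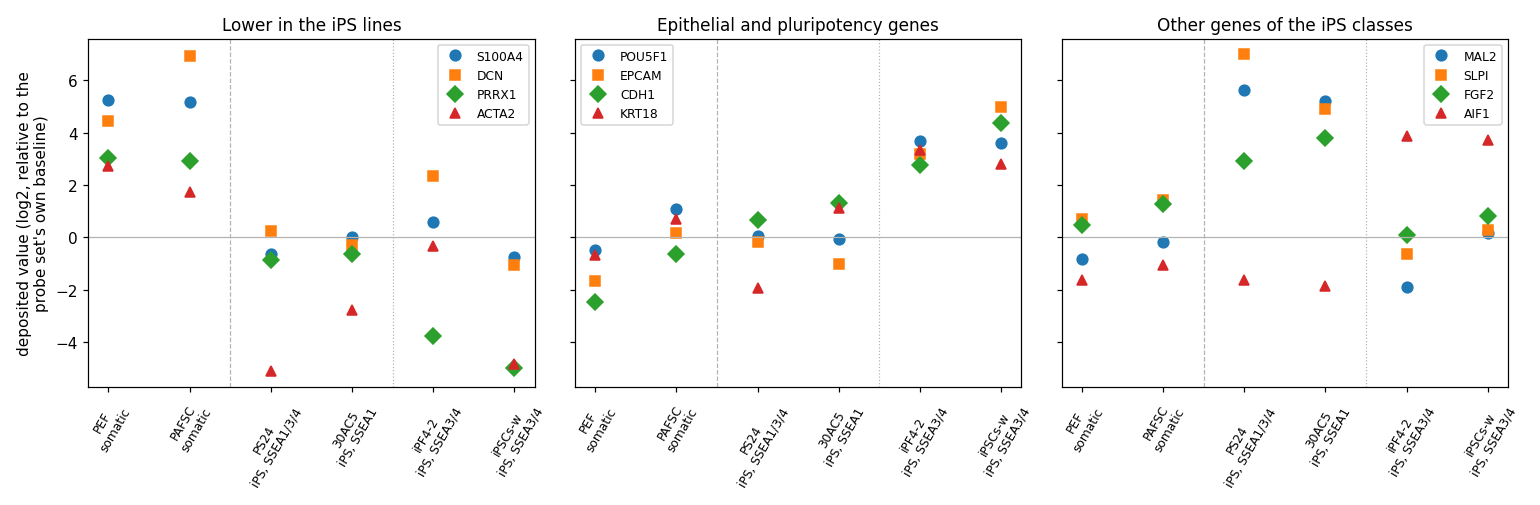
Deposited log2 values of 12 genes (vertical axis, relative to each probe set's own baseline) on each of the 6 arrays (horizontal axis), 1 point per gene and array, with a dashed line between somatic samples and iPS lines and a dotted line between the SSEA1-labelled lines and the SSEA3/SSEA4-only lines. S100A4 was above 5 in both somatic samples, and POU5F1 was 3.68 in iPF4-2 and 3.61 in iPSCs-w.

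The fibroblast and mesenchymal list fell with a median log2 change of -2.92 (camera adjusted p = 5.13e-10; adjusted p = 0.259 with an estimated correlation). Adjusted over the list alone, 14 of its 23 genes passed the threshold, against 1 over all probe sets. The smooth muscle and contractile list fell with a median of -3.65 over 9 genes (camera adjusted p = 1.85e-05; adjusted p = 0.259 with an estimated correlation). Its members included ACTA2, smooth muscle actin, with a difference of -5.49 (SE 1.25), and CNN1, the actin-binding calponin, with -4.80 (SE 0.62, limma adjusted p = 0.0791). Adjusted over the list alone, 5 of the 9 passed, and 0 passed in limma over all probe sets. The ectoderm and neural list fell with a median of -1.59 over 5 genes (camera adjusted p = 0.0142; adjusted p = 0.259 with an estimated correlation). It was led by CRABP2, a retinoic acid binding protein, at -4.70 (SE 0.92), and adjusted over the list alone 2 of its genes passed. With 1 somatic sample left out the ectoderm and neural list lost the call, without PEF (camera adjusted p = 0.158) and without PAFSC (camera adjusted p = 0.0562), and the contractile list lost it without PEF (camera adjusted p = 0.158).

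Lower medians were also called by camera for 3 further lists. They were imprinted genes (-0.84, adjusted p = 0.0250; adjusted p = 0.311 with an estimated correlation), endothelial genes (-0.98, adjusted p = 0.0376; adjusted p = 0.685 with an estimated correlation) and interferon response genes (-0.99, adjusted p = 0.0382; adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone, 1, 1 and 0 of their genes passed. NNAT, an imprinted gene of the neuronatin proteolipid, differed by -3.73 (SE 0.63), and ERG, an endothelial transcription factor, by -4.84 (SE 0.65, limma adjusted p = 0.0805). RSAD2, an interferon-induced antiviral enzyme, differed by -1.68 (SE 0.49). Without PAFSC the endothelial median was 0.12 and camera no longer called it (adjusted p = 0.925), nor did it after quantile normalization (-0.36, adjusted p = 0.181). Without PAFSC the imprinted median was -0.32 (camera adjusted p = 0.0198; adjusted p = 0.416 with an estimated correlation), with 5 of 13 genes positive against 1 before. The imprinted and interferon lists lost the call without PEF, and the interferon list also without iPF4-2.

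Lists of metabolism and proliferation moved the other way. Oxidative phosphorylation genes rose with a median of 1.27 over 20 genes, 20 of them higher in the mean (camera adjusted p = 2.80e-05; adjusted p = 0.354 with an estimated correlation). Cell cycle genes rose with a median of 0.79 over 17 genes (camera adjusted p = 0.0250; adjusted p = 0.259 with an estimated correlation), glycolysis genes with 0.78 over 14 (camera adjusted p = 0.0379; adjusted p = 0.354 with an estimated correlation), and DNA and histone methylation genes with 1.14 over 8 (camera adjusted p = 0.0453; adjusted p = 0.311 with an estimated correlation). Adjusted over the list alone, 0, 0, 0 and 1 of their genes passed. The 1 was JARID2, a partner of the Polycomb complex, at 2.06 (SE 0.48). Much of the size lay in the PAFSC array: COX6C, a subunit of cytochrome c oxidase, was -8.01 there, -0.06 in PEF and 0.09 in 30AC5, and TOP2A, the mitotic topoisomerase, was -7.24 there and -0.09 in PEF. Without PAFSC the medians were 0.41 for oxidative phosphorylation (camera adjusted p = 0.0154) and 0.60 for the cell cycle (camera adjusted p = 0.0197), each with an adjusted p = 0.416 with an estimated correlation. The cell cycle list lost the call without PEF (camera adjusted p = 0.0672). Without PAFSC camera did not call glycolysis (0.33, adjusted p = 0.353) or DNA and histone methylation (0.85, adjusted p = 0.130). These 2 calls did not depend on PAFSC alone: glycolysis lost the call in 8 of 11 settings, among them quantile normalization and leaving out PEF or 30AC5, and DNA and histone methylation in 7 of 11, among them leaving out PEF, 30AC5 or iPF4-2. Without PAFSC camera also called 3 lists that it had not called before: epithelial genes higher (0.99, adjusted p = 0.0197; adjusted p = 0.611 with an estimated correlation), and mesenchymal stem cell surface genes (-0.88, adjusted p = 8.21e-04) and heat shock genes (-0.96, adjusted p = 0.0103) lower, both at an adjusted p = 0.416 with an estimated correlation. In all, camera called 10 of 25 lists, 0 with an estimated correlation and 2 with the lowest 40% of probe sets left out. Fry called 4 of the 25. The estimated correlation was -0.0066 for cell cycle genes and -0.1174 for DNA and histone methylation genes, below the preset 0.01. A higher correlation among genes therefore did not remove these calls.

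**Figure D2:**
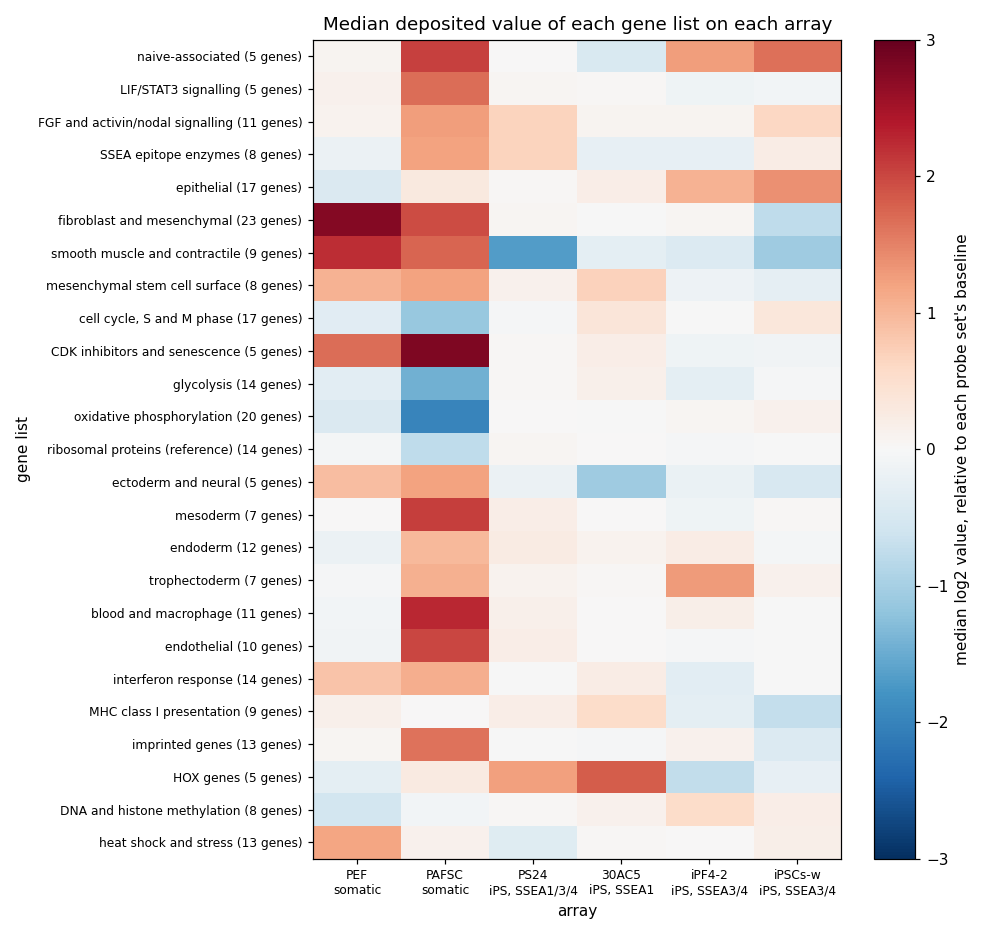
Median deposited log2 value (colour, relative to each probe set's baseline) of the 25 gene lists with 5 or more measured genes (rows) on each of the 6 arrays (columns). The fibroblast and mesenchymal list had medians of 2.76 in PEF and 1.95 in PAFSC, and the oxidative phosphorylation list had -1.98 in PAFSC.

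Across all 23999 probe sets limma called 6, 2 higher and 4 lower in the iPS lines, and S100A4 was the 1 with a gene symbol. At an unadjusted p under 0.05 there were 3276. The 11 other genes named as lower failed the threshold. Among them LOXL1, an enzyme that cross-links elastin, differed by -4.46 (SE 0.60, limma adjusted p = 0.0805), MFAP2, a microfibril protein, by -3.01 (SE 0.45, limma adjusted p = 0.103), and TGFB3, a growth factor, by -2.74 (SE 0.45, limma adjusted p = 0.119). The 12 named as higher failed as well. They included TSPAN33, a tetraspanin, at 3.65 (SE 0.46, limma adjusted p = 0.0791), PPAT, the first enzyme of purine synthesis, at 3.92 (SE 0.59, limma adjusted p = 0.103), and TAF4B, a subunit of a general transcription factor, at 3.25 (SE 0.59, limma adjusted p = 0.151). The 4 iPS lines lay on one side of both somatic samples for 21.9% of probe sets. Chance would give 13.3% if all 6 arrays varied alike. The PAFSC array, with an SD of 2.01, did not, so the excess cannot be read as a difference between iPS and somatic cells.

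The count rested on single arrays. With PAFSC left out limma called 136 probe sets, 13 higher and 123 lower, and with PEF left out 14303; the lone somatic sample was then assumed to vary like the iPS lines. It called 1 without iPF4-2 and 0 without PS24, 30AC5 or iPSCs-w, and with the lowest 40% of probe sets by mean left out it called 35. Against PEF alone, ASPN, the matrix protein asporin, was lower by a log2 change of -8.81 (SE 0.45, limma adjusted p = 0.0120), THBS2, a thrombospondin, by -5.69 (SE 0.26, limma adjusted p = 0.0120), and MYC, a growth-promoting transcription factor, by -5.89 (SE 0.60, limma adjusted p = 0.0351). NUP210, a nuclear pore protein, was higher by 4.67 (SE 0.33, limma adjusted p = 0.0191). These genes were chosen after the PAFSC array had been seen. ASPN was 0.52 and MYC -0.14 in PAFSC.

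The core pluripotency list had 3 measured genes and the reprogramming factor list 3, too few for the list test. POU5F1, which encodes the pluripotency factor OCT4, was -0.50 in PEF, 1.09 in PAFSC, 0.07 in PS24, -0.07 in 30AC5, 3.68 in iPF4-2 and 3.61 in iPSCs-w. DNMT3B, a DNA methyltransferase of early embryonic cells, was -0.75, 0.64, 0.04, -0.12, 1.18 and 2.88 in the same order. ZFP42, also known as REX1, was -0.12, 0.55, -0.69, -0.62, 0.47 and 0.80. KLF4, a reprogramming factor, was 2.12 and 2.79 in the somatic samples and -2.91, -0.63, -0.79 and -0.80 in the iPS lines; its difference of -3.73 (SE 0.73) failed over all probe sets (limma adjusted p = 0.160) and passed adjusted over the 3 reprogramming factors alone. MYC was 5.55 in PEF, -0.14 in PAFSC, and -0.75, 0.15, 0.29 and -1.04 in the iPS lines. Other factors of these lists were not analysed here.

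Of 15 listed glycan enzymes that build or modify the SSEA epitopes 8 were measured. In the iPS against somatic comparison limma called 0, also adjusted over the list alone (camera adjusted p = 0.825). Between the SSEA1-labelled and the SSEA3/SSEA4-only lines the median difference was 0.40, with 6 of 8 positive (camera adjusted p = 0.117). The other listed enzymes were not measured, so these values cannot show how the epitopes are made. In the order PEF, PAFSC, PS24, 30AC5, iPF4-2 and iPSCs-w, ST3GAL1, a sialyltransferase, was 2.18, 1.92, 1.36, -0.23, -0.21 and -0.81, and ST3GAL2, a sialyltransferase that can form SSEA4, was -0.29, 2.10, 0.35, 0.42, 0.16 and 0.16. The fucosyltransferase FUT1 was -0.08, 0.48, 0.68, 0.36, -0.70 and 0.49, and FUT2 was -0.44, 2.16, 0.65, -0.28, 0.22 and -0.41. The galactosyltransferase B4GALT1 was 0.28, -0.43, 1.47, 0.89, -0.28 and 0.40, and B4GALT5 was -0.45, -2.76, 1.20, -0.37, -0.47 and 0.27. B3GALNT1, the globoside synthase, was -0.30, 2.06, -0.01, -0.41, -0.16 and 0.01, and B3GNT5, which starts lacto-series glycolipids, was 0.82, -2.16, -0.03, -0.56, -0.55 and 0.45.

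The second question was how the lines carrying SSEA1 (PS24 and 30AC5) differed from those labelled with SSEA3 and SSEA4 only (iPF4-2 and iPSCs-w). Epithelial genes were lower in the SSEA1-labelled lines, with a median difference of -1.92 over 17 genes, 13 of them negative (camera adjusted p = 2.97e-08; adjusted p = 0.425 with an estimated correlation). EPCAM, an epithelial adhesion molecule, was -0.16 in PS24 and -1.03 in 30AC5, against 3.18 in iPF4-2 and 4.98 in iPSCs-w, a difference of -4.68 (SE 0.91, limma adjusted p = 0.417). CDH1, the epithelial cadherin, differed by -2.60 (SE 0.87), and KRT8, a keratin of simple epithelia, by -3.05 (SE 1.28). Adjusted over the list alone, 4 of the 17 genes passed. The PS24 array, 1 of the 2 in this class, had low 5' signal in control genes: the 5' minus 3' value of GAPDH, actin and EF1A averaged -2.02 relative to the other arrays.

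The list of genes associated with naive pluripotency was also lower, with a median of -1.25 and 5 of 5 genes negative (camera adjusted p = 7.18e-05; adjusted p = 0.425 with an estimated correlation). DPPA5, an RNA-binding protein of pluripotent cells, differed by -3.03 (SE 0.70), and NR0B1, a nuclear receptor, by -1.25 (SE 0.90). POU5F1, which is not in this list, differed by -3.65 (SE 0.72, limma adjusted p = 0.444). Camera called 3 lists higher in the SSEA1-labelled lines. MHC class I presentation genes had a median of 1.47, with 9 of 9 positive (camera adjusted p = 1.40e-06; adjusted p = 0.273 with an estimated correlation), among them TAPBP, the peptide-loading protein tapasin, at 1.90 (SE 0.72). The 5 HOX genes had a median of 1.12 (camera adjusted p = 1.12e-05; adjusted p = 0.273 with an estimated correlation), with HOXA3 at 2.85 (SE 0.84). FGF and activin/nodal genes had a median of 0.38 (camera adjusted p = 0.0139; adjusted p = 0.425 with an estimated correlation), with FGF2, a growth factor used in stem cell culture, at 2.92 (SE 0.69). Adjusted over the list alone, 2 naive-associated, 0 MHC class I, 2 HOX and 1 FGF and activin/nodal gene passed. The estimated correlation of the MHC class I list was -0.0472, below the preset 0.01. A higher correlation among its genes therefore did not remove that call. Over the alternative settings the naive-associated median ran from -2.11 to -0.97 and the FGF and activin/nodal median from 0.16 to 1.17. The MHC class I median ran from 0.85 to 2.15 and the HOX median from 0.61 to 1.62. Without PAFSC camera did not call the FGF and activin/nodal list, and it also lost the call without 30AC5 or iPF4-2. Leaving out PEF gave the same fit as leaving out PAFSC, since a lone somatic array adds nothing to the spread. In that fit camera also called mesenchymal stem cell surface genes higher (median 0.64, 7 of 8 positive), which it had not with all arrays. It did not call them with an estimated correlation.

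No probe set passed the threshold in this comparison: limma called 0 of 23999, with 681 at an unadjusted p under 0.05. The genes named by size therefore failed the test. The 681 were 2.84% of the probe sets, below the share of 0.05 that chance would give. The spread in this test also took in the difference between PEF and PAFSC (SD 2.09 over the probe sets). Without PAFSC more probe sets had an unadjusted p under 0.05, so the 0 does not show that the classes are alike. MAL2, a protein of epithelial vesicle transport, was higher in the SSEA1-labelled lines by 6.28 (SE 0.82, limma adjusted p = 0.214), SLPI, a secreted protease inhibitor, by 6.14 (SE 0.84, limma adjusted p = 0.234), CXCL2, a neutrophil chemokine, by 6.31 (SE 1.20, limma adjusted p = 0.414) and CDH6, a cadherin, by 4.58 (SE 0.94, limma adjusted p = 0.482). HSD17B2, a steroid dehydrogenase, differed by -5.93 (SE 0.84, limma adjusted p = 0.234), AIF1, a calcium-binding protein known from macrophages, by -5.55 (SE 0.61, limma adjusted p = 0.214) and AMY2, an amylase, by -5.19 (SE 1.17, limma adjusted p = 0.608). Without PAFSC, limma called 4 probe sets, and AIF1 was the 1 with a gene symbol (limma adjusted p = 0.0486). The SE of AIF1 was 0.61 with PAFSC and 0.26 without it. After quantile normalization limma called 90, and with the lowest 40% by mean left out 44. The lines of the classes lay apart for 41.2% of probe sets, where chance gives 33.3% if the 4 arrays vary alike. The probe sets of an array are not independent, so the excess alone cannot be read as a difference between the classes.

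Each iPS line was then set against the other 3, and limma called 0 probe sets in each of the 4 comparisons. At an unadjusted p under 0.05 there were 225 for PS24, 261 for 30AC5, 220 for iPF4-2 and 351 for iPSCs-w. These were 0.92% to 1.46% of the probe sets, below the share of 0.05 that chance would give. The lone line was assumed to vary like the other classes, and the spread again took in the difference between PEF and PAFSC. These unadjusted counts rose for every line when PAFSC was left out. The genes with the largest differences are given as values that failed the test. In PS24, SELP, the adhesion receptor P-selectin, was 5.07 and at most 0.20 in the other iPS lines, and KRT18, a keratin, was -1.93 against 1.12 to 3.34. In 30AC5, F3, the coagulation starter tissue factor, was 4.58, near its 4.40 in PEF, and DAB2, an endocytic adaptor, was 4.38 and 4.08 in PEF. In iPF4-2, SLC28A3, a nucleoside transporter, was 5.29 and at most 0.40 in the others, and TOX3, a chromatin protein, was 4.17 and at most -0.48. In iPSCs-w, FBP1, an enzyme of gluconeogenesis, was 5.56 and at most 1.55 in the others, IFIT3, an interferon-induced protein, was 4.26 and at most 0.26, and LEF1, a transcription factor of Wnt signalling, was -2.92 against 1.35 to 1.69.

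The 2 somatic samples had 1 array each and were compared without a test. PEF was over 2 log2 units above PAFSC for 3903 probe sets and over 2 below for 4832; together these were 8735, and 1921 after quantile normalization. Of the genes named by size, ASPN was 8.74 in PEF against 0.52 in PAFSC, COL15A1, a collagen, 6.32 against -0.08, NFKBIA, an inhibitor of NF-kappaB, 2.30 against -3.85, POSTN, periostin, 7.11 against 1.17, and LUM, lumican, 7.34 against 1.59. The chemokine CXCL8 was 6.59 against 0.86. In PAFSC, FGF7, a growth factor for epithelia, was 8.12 against -0.06 in PEF, MSMO1, an enzyme of sterol synthesis, 7.38 against -0.03, and TIMP3, an inhibitor of metalloproteinases, 8.20 against 2.33.

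The similarity of the arrays was described by Pearson's r across 23999 probe sets, which are not independent replicates. The values are relative to the baseline of each probe set, so r compares deviations from it and not whole expression profiles. A low or negative r therefore does not mean that 2 samples share little expression. PS24 and 30AC5 had r = 0.430 and iPF4-2 and iPSCs-w r = 0.405, while the 4 pairs across these classes had 0.047 to 0.124. PEF had 0.126 with 30AC5 and -0.252 with iPSCs-w. The first principal component held 65.5% of the variance and set PAFSC apart from the other 5 arrays.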

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

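All tests of explanations in this part were chosen after related values had been seen.

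Camera called 5 lists in the direct test between the SSEA1-labelled and the SSEA3/SSEA4-only lines. It called 0 with an estimated correlation (smallest adjusted p = 0.273 with an estimated correlation), fry called 0, and limma called 0 probe sets. The median differences were -1.92 for epithelial, -1.25 for naive-associated, 1.47 for MHC class I presentation, 1.12 for HOX and 0.38 for FGF and activin/nodal genes. Among 32 genes named in the 2 main comparisons, SHROOM3 in 30AC5 lay far from the other iPS lines, at 1.94 against 0.92 to 1.00; chance gives about 1 such gene in 20. Reporter control probe sets, meant for marker and vector sequences, gave a signal that the comparisons did not use: in iPF4-2, 5 of 64 lay over 1.5 log2 units above PEF and the other iPS lines, at 2.25 to 3.43, against at most 0.73 there and up to 2.29 in PAFSC. No explanation was tested for these 5.

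The PAFSC array stood apart from the other 5. If this were a difference of the cells alone, 2 probe sets of a gene would move together as on the PEF array, but their correlation over 2261 genes was 0.296 against 0.602, a difference of -0.31 (95% bootstrap interval -0.37 to -0.23); the low value is not particular to PAFSC, since PS24 had 0.337 and the other iPS lines 0.514 to 0.614. RNA shortened towards the 3' end stays open, since the 5' minus 3' values of 3 control genes went both ways, with a mean of 0.22. Probes that do not match the hybridised RNA also stay open: the spread within genes over the SD of the array was 1.04 times the next highest array (interval 0.963 to 1.12), and a second measure, added later, which divides by the spread between random probe sets, gave 0.809 and pointed the other way. A part of the difference may still come from the cell type, which was not tested apart from the array.

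The PS24 array had low 5' signal in GAPDH, actin and EF1A. RNA degraded in the culture would leave the spiked-in polyadenylated controls intact, but their 5' minus 3' value averaged -1.75 over 4 controls (SD 0.98), with all 4 below 0. A candidate explanation is a shortened product in the labelling reaction, which needs this loss in the controls. No biological explanation was tested, since the design gives none.

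The SSEA3/SSEA4-only lines lay above the SSEA1-labelled lines in epithelial genes. A batch in hybridization shared within a class would bring its hybridization controls together. The closest pair of arrays crossed the classes instead (by -0.45, interval -0.58 to -0.30). That interval resampled only 9 control probe sets, and iPSCs-w was low in 1 control (bioB -2.90). These controls cannot show a batch in culture, RNA preparation or labelling, which stays open. Dilution by mouse feeder RNA would lower genes above PEF as much as epithelial genes. Over 604 such genes the median difference was -0.34 (interval -0.42 to -0.28), against -1.92 for the epithelial list. At that epithelial median this argues against dilution as the whole cause. The distance of 1.58 had an interval of -0.29 to 2.25, because the interval of the epithelial median reached -0.04. Dilution as a part of the cause stays open. Pig fibroblasts left in the SSEA1-labelled lines would need PEF genes near their PEF level, at -0.44 if they were the whole cause. The fibroblast list lay at -2.74 (interval -4.30 to -1.45) and 151 genes high in PEF at -3.06 (interval -3.48 to -2.78). At the observed epithelial median these values argue against fibroblasts as the whole cause. The distance of -2.62 from the needed level had an interval of -3.11 to 1.62, because that median was uncertain. At an epithelial median of -0.04, the end of its interval, little difference would be left to explain. Fibroblasts as a part of the cause stay open. The 5' loss of PS24 stays open too: with PS24 left out camera still called the epithelial list at a median of -1.31 (adjusted p = 7.50e-06; adjusted p = 0.448 with an estimated correlation), but this rests on 30AC5 alone and its interval ran from -1.96 to 0.04. A difference of marker class, and a difference of laboratory, which the labels do not give, were not tested and may contribute.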

How the results depend on the processing

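No paired analysis was possible because the labels give the samples no shared replicate numbers. The settings that leave out PAFSC and PS24 together, or PAFSC or PS24 with an estimated correlation, were added after seeing the data; a line's own comparison has no value without that line. For iPS against somatic, limma called 6 probe sets, 4 after quantile normalization (0 of them higher, against 2), 1 after median centring, 35 without the lowest 40% by mean, 61 with low values raised to the 25th percentile, 2 with a trend, 0 with treat, 0 with 1 probe set per gene, 0 with 4 classes and 0 without PAFSC and PS24. Leaving out single samples gave 0 to 14303: 14303 without PEF, 136 without PAFSC, 1 without iPF4-2 and 0 without PS24, 30AC5 or iPSCs-w. The median change over all probe sets was -0.34, and -0.04 after quantile normalization or centring, so a change is to be read against that shift. For the SSEA1 comparison, 0 became 90 after quantile normalization, 44 without the lowest 40% and 4 with only the 4 iPS lines, and 0 to 4 with single samples left out (4 without PEF or PAFSC). In that comparison, leaving out PEF, leaving out PAFSC and using only the 4 iPS lines are the same fit, so they count as 1 setting. Each line against the others has 1 line in the arm, so a count of 0 in all settings run says nothing about stability. Called lists numbered 10 for iPS against somatic, 2 without the lowest 40%, 4 with fry, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 0 with it and PAFSC left out, and 5 to 11 with single samples left out (5 without PEF). For the SSEA1 comparison 5 became 3 without the lowest 40%, 9 without PAFSC and PS24, 0 with fry, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 0 with it and PAFSC left out, and 5 to 8 with single samples left out (8 without PS24 or iPSCs-w). In 173 repeats of the 15 called lists none reversed its direction in the test and 57 lost the call; the median alone changed sign in a setting for cell cycle (lowest -0.27) and endothelial genes (highest 0.12). Probe sets over 2 log2 units apart between PEF and PAFSC were 8735, 1921 after quantile normalization and 5106 without the lowest 40%. The correlation of PS24 and 30AC5 was 0.410 after quantile normalization and 0.302 with Spearman, and that of iPF4-2 and iPSCs-w 0.366 without the lowest 40% and 0.287 with Spearman. Of 2688 repeats for 189 named differences 58 changed sign, all of genes that had not passed the threshold. Almost no named gene had passed it, so this was nearly fixed in advance. The trend, robust, treat and low-mean settings leave a difference unchanged. Genes named for a lack of overlap keep their sign when a sample is left out. The 58 is therefore no measure of stability. With single samples left out, the log2 differences between iPS lines and somatic samples that changed sign ranged over these values: PTPRC -2.49 to 0.12, CD163 -2.36 to 0.074, CDKN2C -2.83 to 0.14, CDKN2B -2.88 to 0.78, GADD45A -2.15 to 0.52, GFAP -3.33 to 0.15, TEK -2.90 to 0.13, CDH5 -2.18 to 0.10, HOXD10 -0.12 to 1.39, SOCS3 -2.03 to 0.11, JAK1 -2.06 to 0.27, IL6R -1.18 to 0.33, ITGB1 -0.94 to 3.89, GSC -2.45 to 0.11, TAP1 -1.97 to 0.23, PSMB8 -2.36 to 0.76, NR0B1 -0.34 to 2.07, DPPA5 -0.053 to 1.26, B3GALNT1 -2.20 to 0.15, FUT2 -2.12 to 0.49, PPAG3 -3.17 to 0.45, TFAP2C -0.19 to 2.44, ZFP42 -0.56 to 0.11, FUT1 -0.28 to 0.31, B3GNT5 -0.997 to 1.99 and ST3GAL2 -1.83 to 0.56. Without PAFSC and PS24 they were PTPRC 0.092, LCP1 0.16, CD163 0.082, CDKN2C 0.11, CDKN2B 0.75, TEK 0.18, CDH5 0.018, SOCS3 0.10, JAK1 0.15, IL6R 0.26, ITGB1 -0.98, GSC 0.072, TAP1 0.22, PSMB8 0.50, B3GALNT1 0.11, FUT2 0.28, PPAG3 0.34, ZFP42 0.34, B3GNT5 -1.04 and ST3GAL2 0.53. After quantile normalization they were IL6R 0.23, B2M 0.32, B3GNT5 -0.43 and ST3GAL2 0.25. With low values raised they were ITGB1 -0.25 and B3GNT5 -0.31. After centring they were ZFP42 0.075. The cause was not tested; leaving out PAFSC, with its wide values, changes the somatic mean by construction.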

Other observations

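Some further genes separated the iPS lines, given here as values. GATA6, a factor of primitive endoderm, was 3.45 in iPF4-2 and 3.57 in iPSCs-w, against 0.53 in PS24 and 0.63 in 30AC5. TFAP2C, a factor of trophectoderm and germ cells, was 2.89 and 2.65 against -0.04 and 0.04. KIT, a receptor of germ cells, was 2.50 in iPSCs-w and at most 0.70 in the other iPS lines. GATA2, a factor of blood and trophectoderm, was 3.54 in PS24, 2.06 in iPF4-2, 1.77 in iPSCs-w and 0.01 in 30AC5. In the endoderm, trophectoderm, naive-associated and FGF and activin/nodal lists the median and mean against somatic had opposite signs, and camera called none of these 4 there.

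Some genes high in PEF were not low in every iPS line. LUM was 3.77 and POSTN 3.01 in iPF4-2, against at most -0.02 and 0.20 in the other iPS lines, while ASPN was -0.10 there and 8.74 in PEF. EIF1AY, a gene of the Y chromosome, was -0.06 in PS24 and 0.22 in iPF4-2, -6.42 in 30AC5, -6.42 in iPSCs-w, -6.27 in PEF and -3.11 in PAFSC. The hybridization control bioB was -2.90 on iPSCs-w and 1.90 on PAFSC.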
